A study of Homo sapiens with 5 samples.

How the data were processed

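Methylated DNA immunoprecipitation followed by sequencing (MeDIP-seq), in which an antibody against 5-methylcytosine pulls down methylated DNA fragments, was applied to 5 cultures of K562, a human chronic myeloid leukaemia cell line. Per the labels, 2 were wild type (a bulk culture and a transfected line) and 3 were DNMT3A-mutated lines (MT1, MT2 and MT4). Libraries were sequenced as paired ends of 100 to 125 bp at a stated target of about 40 M reads per sample, per the labels' protocols. Bowtie 1.1.1, edgeR and the genome build hg19 are named in the submitters' processing notes. The role of each tool, the peak caller's version and threshold and the use of an input control are not given in the sources used here.

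The deposited files hold 1 peak list per library, so that peaks had been called by the authors for each library alone and not on pooled libraries. Each line gives the start and end of a peak, in base pairs, and a score. The peak names in the deposited files begin with the name of the caller MACS. The score of each peak, as deposited by the authors, ran from 90 upwards in all 5 lists, which fixes the lowest score kept; it was used only to rank or filter peaks within a list, and its comparison between libraries describes the lists. No read counts per peak and no read totals per library were used here, so the depth behind a single peak is unknown. A peak missing from a list is a site that did not reach the score limit in that library. Lower methylation and lower sensitivity cannot be told apart for such a site. No count model was fitted.

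From these lists the number of peaks, the base pairs covered, the median width and the median score were computed per library (Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1). Peaks of the 5 lists that overlapped by at least 1 bp were merged into regions, and each region was described by the libraries that held a peak in it. The Jaccard index is the number of base pairs covered in both lists divided by the number covered in either. Overlap expected from random placement was taken from 100 seeded placements of each peak on its own chromosome, between the first and last peak of any list. Recovery is the percentage of the regions with a peak in at least 2 of the other 4 libraries that also had one in the library in question; intervals are 95% Wilson intervals. They cover counting error only, regions near one another are not independent, and fragments amplified by PCR are not independent molecules. Runs of 10 Mb bins with a shortfall of recovery were searched over all chromosomes, and the largest shortfall of a library was set against the same search in 1000 permutations of its hits among regions held by as many other libraries; this search was added after the data were seen. Shares of peaks were also taken over chromosomes 1 to 22 and X and over windows of 1 Mb, where a peak belongs to the window of its start. Coordinates are hg19, counted from 1.

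The library was the replicate. The 2 wild-type libraries, a bulk culture and a transfected line, are different kinds of control and not repeats of the same culture. Effects of culture history therefore cannot be separated from those of genotype in this design. Wild-type and mutated libraries were compared with an exact permutation test of the difference of means, two-sided, over the 10 ways to choose 2 of 5 libraries. This design cannot give a p below 0.2. Numbers of regions held by exactly one genotype were set against the same numbers for the other 9 choices, a share that cannot be under 0.1. The labels do not state whether the 3 mutated lines came from separate editing events, and p-values of genotype comparisons measure only the spread between these libraries. The permutation p-values of the search for low recovery measure the spread among regions within a single library. They treat neighbouring regions as independent and say nothing about other cultures. Merging and overlap were tested on simulated lists, in which all 200 planted regions of both wild-type and no mutated library, and all 200 of the reverse class, were recovered. Planted regions lay far apart and were never missed in a library meant to hold them. The simulation checks the counting, not the effect of missed or neighbouring peaks.

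Choices made before the data were examined were the groups, the tests, the alternatives and the rule for the regions named in the text. That rule took the top 10 regions, by the mean percentile of the caller score within each list holding them, among regions in all 3 mutated and no wild-type library, in both wild-type and no mutated library, and in all 5 libraries, and the 10 windows of 1 Mb with the largest difference in share of peaks in which all mutated libraries lay on one side of both wild-type libraries. Alternatives were a score limit at 121.64, the median of all peaks; lists limited to the 1426 best-scoring peaks, the length of the shortest; chromosomes 1 to 22 and X only; an overlap of at least 50% of the shorter peak; a gap of up to 500 bp; and leaving out each library in turn. Leaving out chromosomes 4 and 7 was added after the data were seen, as were the alternatives for the windows and some of those for width and score.

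The gene table used here describes another genome build (GRCh38.p14), so peaks were not assigned to genes, promoters or CpG islands, and the gene lists drawn up beforehand (DNA methylation machinery, splicing factors, DNA repair, haematopoietic regulators, HOX genes, imprinted genes, germline genes, protocadherins, Polycomb targets and tumour suppressors) were not tested. Where a gene cluster is named beside a segment, this is general knowledge of hg19 and not an annotation.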

Results

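DNA methylation was profiled by MeDIP-seq in 5 cultures of K562, a chronic myeloid leukaemia line that carries the BCR-ABL1 fusion. The comparison was between 2 wild-type cultures (bulk and transfected) and 3 lines with mutated DNMT3A, the gene of a de novo DNA methyltransferase (MT1, MT2 and MT4). The lists held 23350 peaks in all, between 1426 and 8399 per library. Peak positions carry no information on the edited DNMT3A sequence, so the genotype labels were taken as given.

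The first question was whether DNMT3A-mutated lines had fewer or smaller methylated regions than wild-type cells. The mutated lines did not lie on one side of the wild-type cultures. MT4 had the most peaks of the 5 libraries (8399) and MT2 the fewest (1426). MT1 had 2842 peaks, wild-type bulk 6213 and wild-type transfected 4470. The mean was 4222 ± 3686 peaks (SD, n = 3) in mutated and 5341.5 ± 1232 (SD, n = 2) in wild-type libraries, a difference of -1119 peaks (exact permutation test, two-sided, p = 0.8; smallest possible p 0.2). Without MT2 the difference became 279.0 peaks, and without MT4 it was -3207.5.

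Peaks covered 10.9 Mb of the genome in MT4, 4.32 Mb in MT1 and 2.79 Mb in MT2, against 9.16 Mb in wild-type bulk and 6.16 Mb in wild-type transfected cells. The group means were 6.01 ± 4.32 Mb (SD, n = 3) and 7.66 ± 2.12 Mb (SD, n = 2), with an exact two-sided permutation p of 0.6. The difference of -1.65 Mb became -0.148 Mb without wild-type bulk, -3.15 Mb without wild-type transfected, -0.808 Mb without MT1, -0.039 Mb without MT2 and -4.10 Mb without MT4. Peak width ran opposite to peak number at both extremes of the mutated group. The median width was 1783 bp in MT2 and 1085 bp in MT4, with 1335.5 bp in MT1, 1255 bp in wild-type bulk and 1183 bp in wild-type transfected cells (exact permutation p = 0.8). The median caller score was 117 ± 6.29 (SD, n = 3) in mutated and 123 ± 3.33 (SD, n = 2) in wild-type lists (exact permutation p = 0.4). Differences between the mutated lines exceeded the difference between genotypes for the number, extent and width of peaks.

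**Figure D1:**
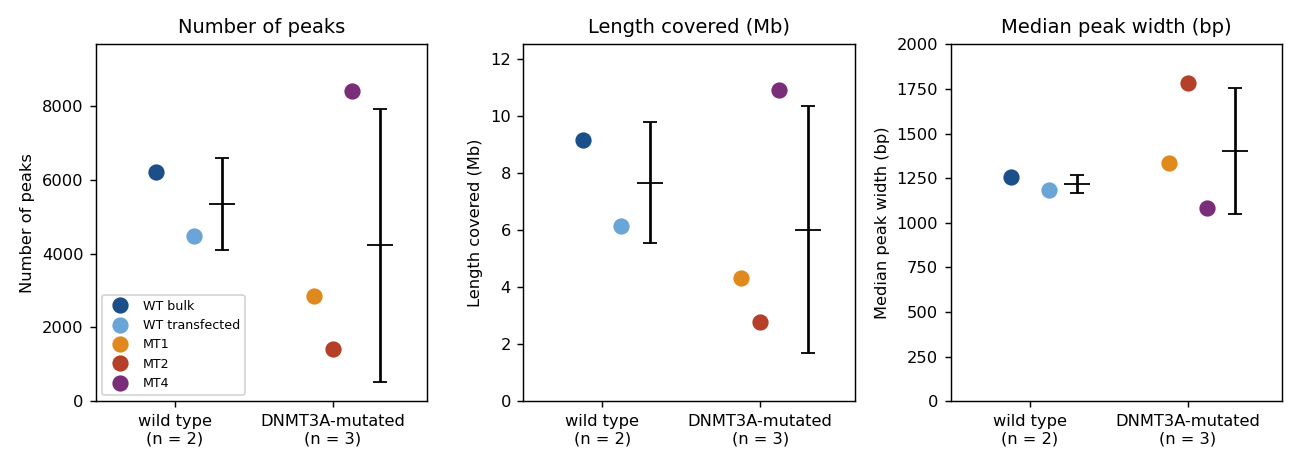
Number of MeDIP peaks, megabases covered and median peak width in base pairs for each library, by genotype; points are libraries and black bars the group mean ± SD. In all 3 panels both wild-type points lie between MT4 (8399 peaks) and MT2 (1426 peaks).

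The second question was which regions had a peak in one genotype and not in the other. Merging gave 11260 regions. Of these, 835 (7.42%) had a peak in all 5 libraries and 5618 (49.89%) in a single library. MT4 alone accounted for 3388 of the single-library regions, wild-type bulk for 1356 and MT2 for 70. Peaks found in no other list made up 40.3% of MT4 peaks (95% Wilson interval 39.3 to 41.4%), 21.8% of wild-type bulk peaks (20.8 to 22.9%), 13.1% of wild-type transfected peaks (12.1 to 14.1%), 7.74% of MT1 peaks (6.81 to 8.78%) and 4.91% of MT2 peaks (3.90 to 6.16%).

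Regions with a peak in both wild-type cultures and in no mutated line numbered 308. This was the third largest of the 10 numbers for a pair of libraries: 1016 regions were held by wild-type bulk and MT4 alone, and 423 by wild-type transfected and MT4 alone. Regions with a peak in all 3 mutated lines and in neither wild-type culture numbered 8, the ninth of the 10 numbers for a trio, where the largest was 897 for both wild-type cultures with MT4. Other groupings of the same libraries gave larger numbers in both cases. These ranks depend on list length, since long lists share more regions. The model of library sensitivity described below expected 1076 regions for wild-type bulk with MT4 and 473 for wild-type transfected with MT4. It expected 221 for the wild-type pair. For the trios it expected 867 and 11.1. The ranks on the full lists are therefore not evidence on genotype. With every list limited to its 1426 best peaks the wild-type-only count was 69, the joint highest with that of wild-type bulk and MT4, and the mutant-only count was 26, in position 9 of 10. Leaving out a library also moved them: the wild-type-only count was 892 without wild-type bulk, 1665 without wild-type transfected and 1205 without MT4, and the mutant-only count was 72, 24, 40, 147 and 18 without wild-type bulk, wild-type transfected, MT1, MT2 and MT4 respectively.

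**Figure D2:**
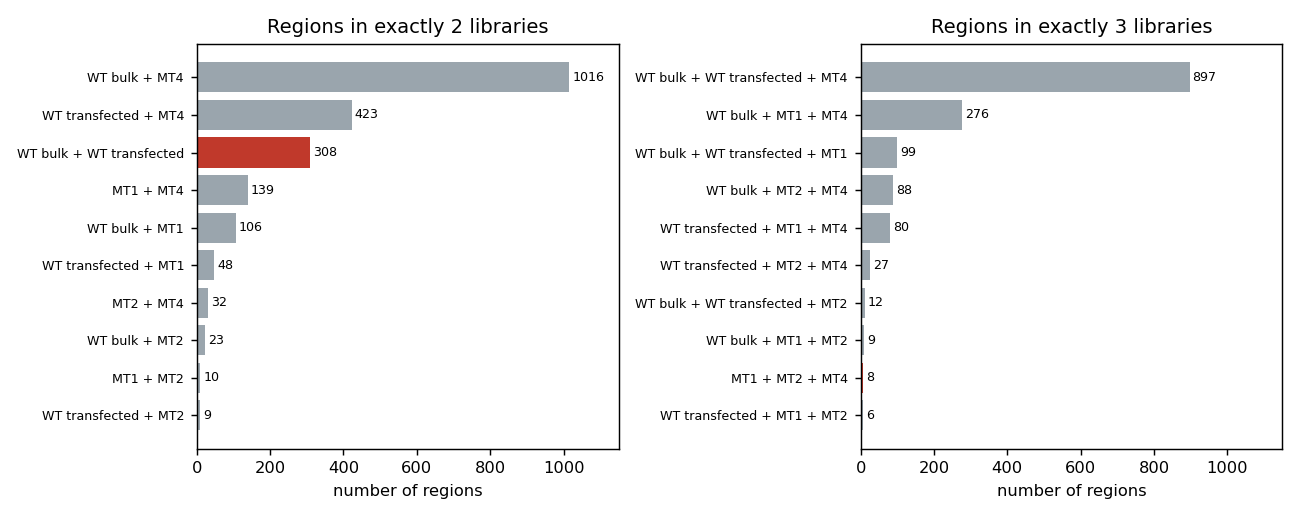
Number of merged regions held by exactly 2 libraries (left) or exactly 3 libraries (right), for each of the 10 combinations; red bars are the 2 combinations that follow genotype. The wild-type pair held 308 regions and the mutant trio 8, below combinations that include MT4 with a wild-type culture (1016 and 897). The order of the bars depends on list length, and MT4 has the longest list.

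The wild-type-only regions were weaker than those common to all libraries. Their median score percentile was 37.6 (quartiles 23.8 to 50.2), against 77.3 (65.9 to 88.5) for the 835 common regions. Regions that reach the score limit in every list tend to score high. No other pair of libraries was compared in this way, so the contrast is not evidence on genotype. The strongest was on chromosome 4, from 127691645 to 127692924, with scores of 256 in bulk and 249 in transfected wild-type cells and a mean percentile of 95.5. The next were on chromosome 15 from 44486563 to 44488018, on chromosome 4 from 132671277 to 132672032, on chromosome 10 from 63422369 to 63423240 and on chromosome 7 from 64717674 to 64718798, with mean percentiles from 80.9 down to 78.7. The remaining 5 of the top 10 were on chromosome 2 (24397336 to 24398664 and 161263454 to 161264839), chromosome 1 (46931335 to 46933487), chromosome X (74143740 to 74145075) and chromosome 17 (30437535 to 30438581). Both chromosome 4 regions lie on a chromosome on which MT4 had few peaks, as described below for single chromosomes.

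The 8 mutant-only regions had a median score percentile of 38.4. The strongest lay on chromosome 7 from 151937268 to 151939056, with scores of 117 in MT1, 119 in MT2 and 141 in MT4. The second lay on chromosome 11 from 7040520 to 7042285 (97.3, 130 and 165 in the same order) and the third on chromosome 8 from 18871362 to 18872649 (105, 121 and 132). The others were on chromosome 9 (136854648 to 136857643), chromosome 4 (159680149 to 159681197 and 73385767 to 73387097), chromosome 17 (66203179 to 66205205) and chromosome 6 (28410717 to 28412761), with mean percentiles between 38.5 and 13.5. At a score limit of 121.64, the median of all peaks, no region fell in this class. This limit lay above the median score of MT1 (117.3), MT2 (110.7) and wild-type transfected cells (121.0). It lay below that of wild-type bulk (125.7) and MT4 (123.3). It thus removed a larger share of the MT1 and MT2 lists than of wild-type bulk or MT4. The loss of this class is therefore not evidence on genotype.

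Regions common to all 5 libraries were headed by peaks with scores at or near the top of each list. The region on chromosome 21 from 9825246 to 9827935 and that on chromosome 7 from 61967995 to 61971328 scored 3100 in every library. This was the highest score of the wild-type bulk, MT1, MT2 and MT4 lists, so ties at 3100 may reflect a limit of the score and not equal signal. The use of an input control is not known, so these scores cannot be read as a measure of methylation. They were followed by regions on chromosome 4 (190942042 to 190944403), chromosome 6 (58775437 to 58779629), chromosome 1 (121482318 to 121485637 and 91852183 to 91853829), chromosome 8 (86746302 to 86748238), chromosome 17 (41399138 to 41401773), chromosome X (108296852 to 108298041) and chromosome 18 (111328 to 113293), all with mean percentiles of 99.7 or more. Those on chromosomes 6 and 7 and the first of the pair on chromosome 1 lie beside centromeres.

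The third question was whether libraries of one genotype resembled each other more than libraries of different genotypes. All lists overlapped far beyond random placement. Between 15.1% and 88.2% of the peaks of one list were overlapped by another, where random placement gave at most 1.11% on average. Of MT2 peaks, 88.2% (95% Wilson interval 86.4 to 89.8%) overlapped a peak of MT4 and 87.5% (85.7 to 89.1%) one of wild-type bulk. Of MT1 peaks, 81.4% (79.9 to 82.8%) overlapped one of MT4 and 81.4% (79.9 to 82.8%) one of wild-type bulk. No peak had identical ends in any pair of lists. The highest Jaccard index was that of the wild-type pair, 0.406, followed by wild-type bulk with MT4, 0.401, and the lowest that of MT2 with MT4, 0.169. The mean was 0.282 over the 4 pairs within a genotype (0.169 to 0.406) and 0.315 over the 6 pairs between genotypes (0.205 to 0.401), a difference of -0.033 (exact permutation p = 0.6). At equal list length the difference was -0.025 (exact permutation p = 0.2, the smallest possible). In that comparison the wild-type pair stood highest at 0.439, and the 3 mutant pairs ranged from 0.307 to 0.330. Without MT4 the difference was 0.059.

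The fourth question was where in the genome peak shares differed. Chromosome 1 held the most peaks in every library, from 11.4% of MT2 peaks to 14.2% of MT4 peaks. Chromosomes 5 and 18 had higher shares in all mutated than in both wild-type libraries, and chromosome 16 a lower share. The mean share of chromosome 5 was 6.75 ± 1.03% (SD, n = 3) in mutated and 5.80 ± 0.01% (SD, n = 2) in wild-type libraries, that of chromosome 18 was 2.33 ± 0.13% against 1.94 ± 0.15%, and that of chromosome 16 was 2.71 ± 0.35% against 3.05 ± 0.01%. These 3 of 23 chromosomes are 13%, where random order alone would separate 20%, and after Benjamini-Hochberg adjustment over the 23 chromosomes every exact permutation p was 1. Leaving out one library gave 6 to 9 separated chromosomes, since fewer libraries are easier to separate.

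Single libraries departed more from the rest than genotypes did. On chromosome 4, MT4 had 137 peaks, 1.63% of its list, where the other 4 libraries had 4.70 to 5.68%. MT4 recovered 50.5% of chromosome 4 regions (102 of 202; 95% Wilson interval 43.7 to 57.3%) and 85.4% of regions elsewhere (84.3 to 86.5%). Of the regions held by both wild-type cultures, 161 on chromosome 4 and 3101 elsewhere, MT4 held 56.5% (48.8 to 63.9%) on chromosome 4 and 87.8% elsewhere. The shares were 61.5% (53.8 to 68.7%) and 56.7% in MT1, and 36.6% (29.6 to 44.3%) and 32.4% in MT2. On chromosome 7 below 60 Mb, wild-type transfected cells recovered 25% of regions (26 of 104; 17.7 to 34.1%), against 62.8% (57.5 to 67.9%) on the rest of the chromosome. Recovery on that segment and elsewhere was 25% and 64.4% in wild-type transfected cells, 85.3% and 80.9% in wild-type bulk, 42.4% and 43.4% in MT1, 25.5% and 23% in MT2, and 91.0% and 83.6% in MT4. The limit of 60 Mb was chosen after the values were seen.

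**Figure D3:**
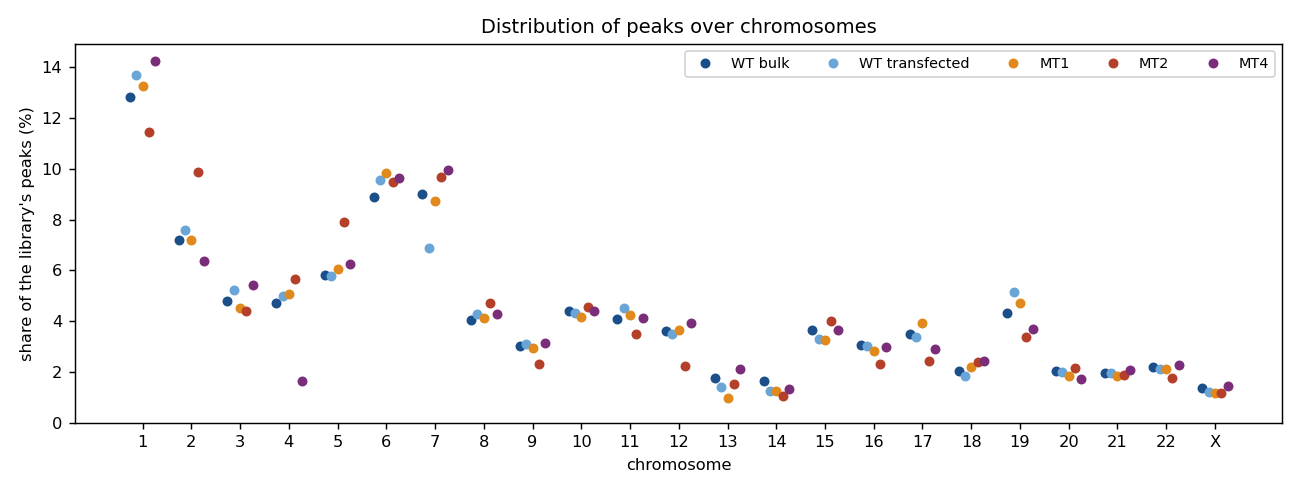
Share of each library's peaks, in percent, on chromosomes 1 to 22 and X; each point is 1 library. MT4 stands apart on chromosome 4 (1.63%, others 4.70 to 5.68%) and wild-type transfected on chromosome 7 (6.87%, others 8.73 to 9.97%).

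**Figure D4:**
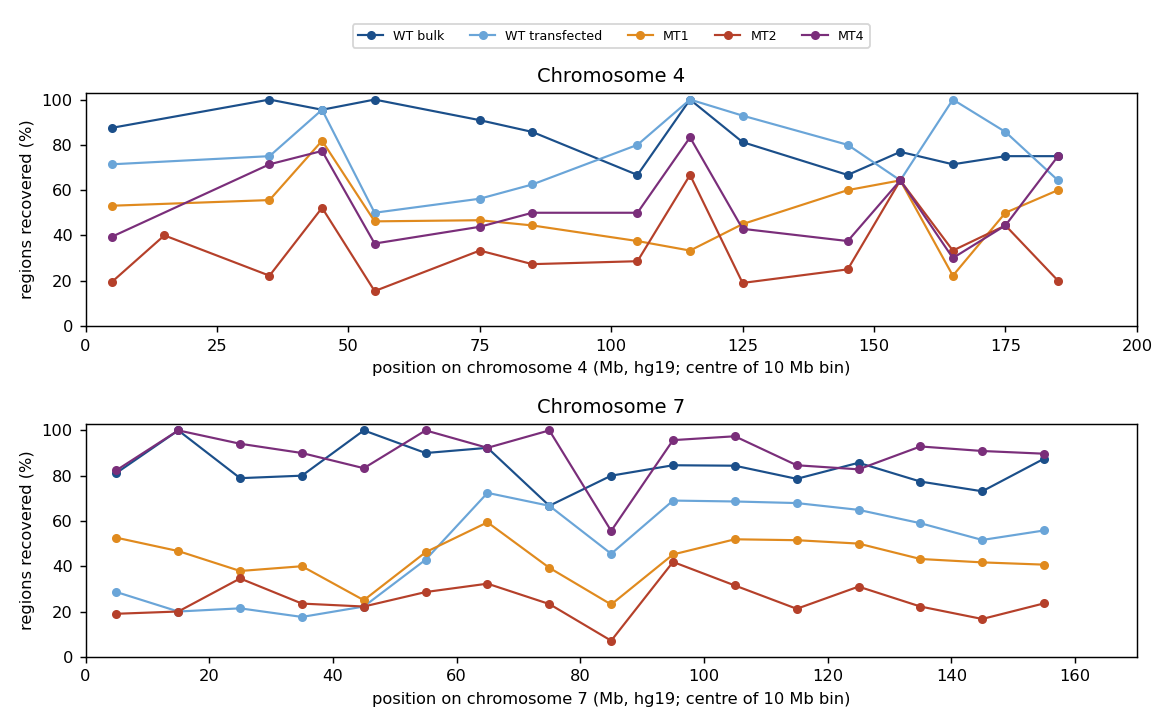
Percentage of regions found in at least 2 other libraries that were also found in the library shown, in bins of 10 Mb along chromosomes 4 and 7 (hg19), for bins with at least 5 regions. MT4 lies below its genome-wide value in all 14 such bins of chromosome 4, and wild-type transfected cells below theirs in all 6 bins of chromosome 7 up to 60 Mb.

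Among the 2183 windows of 1 Mb with a peak, the mutated libraries all lay above both wild-type libraries in 132 and below both in 214. The total of 346 (15.8%) was in position 4 among the 10 ways to choose 2 libraries, and the highest number, 625, was reached by MT1 and MT2 against the rest. These are the shortest lists (2842 and 1426 peaks), and a window without a peak has a share of 0. Short lists therefore tend to lie below the others together, which can also raise the 214. The ranking is not evidence on genotype. Without wild-type bulk, wild-type transfected, MT1, MT2 or MT4 the total was 700, 711, 560, 609 and 777, and at equal list length 77. Among these 346 windows, the largest falls in share were on chromosome 21 at 46 to 47 Mb (0.191% of wild-type and 0.067% of mutant peaks), chromosome 22 at 19 to 20 Mb (0.271% and 0.15%), chromosome 4 at 124 to 125 Mb (0.123% and 0.027%), chromosome 11 at 67 to 68 Mb (0.104% and 0.012%) and chromosome 19 at 46 to 47 Mb (0.143% and 0.059%). MT2 had no peak in any of these 5 windows, and the window on chromosome 4 lies on the chromosome on which MT4 had few peaks (1 peak in the window). The largest gains among them were on chromosome 19 at 37 to 38 Mb (0.123% and 0.235%), chromosome 15 at 22 to 23 Mb (0.047% and 0.157%), chromosome 13 at 92 to 93 Mb (0.077% and 0.184%), chromosome 1 at 43 to 44 Mb (0.104% and 0.204%) and chromosome 7 at 107 to 108 Mb (0.194% and 0.279%). In each of these gains the MT2 share rests on 4 to 6 peaks. With 2 against 3 libraries no window can reach an exact p under 0.2.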

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

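No exact test of a difference between genotypes could pass 0.05 under any setting, as at most 10 groupings allow no p below 0.2. No paired analysis was made, as the labels pair no wild-type culture with a mutated line. The difference in the number of peaks ranged from -3207.5 to 279.0 when each library was left out in turn, with the sign reversed without MT2; that in median width ranged from -8.8 to 340.2 bp, reversed without MT2; and that in the Jaccard index from -0.0760 to 0.0592, reversed without MT4. The difference in covered length turned from -1.65 Mb to 0.143 Mb at equal list length, where every list has as many peaks, and kept its sign in the other 8 settings, though it ranged from -4.10 to -0.039 Mb without one library (lowest without MT4, nearest 0 without MT2). The difference in median score, -6.2, kept its sign in all 7, and was -3.0 without MT2, -3.9 without wild-type bulk and -9.3 without MT4. The number of wild-type-only regions was 179 at the stricter score limit, 69 at equal list length and 322 to 1665 without one library; the number of mutant-only regions was 0, 26 and 18 to 147, and 5 without chromosomes 4 and 7, which were left out after the data were seen. Fewer libraries to satisfy raise such numbers by construction. With fewer peaks the direction depends on which lists lose them: the mutant-only number went from 8 to 0 at the stricter limit and to 26 at equal list length. The stricter limit removed a larger share of the MT1 and MT2 lists than of wild-type bulk. Equal length shortened both wild-type lists and kept all 1426 MT2 peaks. Windows separating the genotypes numbered 77 at equal list length and 560 to 777 without one library, and chromosomes 6 to 9 without one library. Requiring an overlap of 50% or allowing a gap of 500 bp gave 310 and 308 wild-type-only regions and 8 mutant-only regions each; over regions instead of base pairs the Jaccard difference was -0.034 with each, as with 1 bp. The comparisons by genomic feature and by gene list were not run, for want of an annotation in hg19. The fixed score limit and the lack of read totals limit all absences. A region missing from MT2 or MT1 did not reach the score limit there. Whether it was less methylated or was missed by that library cannot be told, so it cannot be called unmethylated.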

Other observations

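Tests by search for low recovery, of empty bins and of traits common to the mutated lines were chosen after the result was seen, as were the segments in the next paragraph; the tests of rank, of width at common regions and of fitted sharing were set out before their results were seen.

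Peaks were concentrated in a few segments in every library. The segment of chromosome 22 from 17 to 24 Mb, which includes BCR, part of the fusion gene that K562 carries in multiple copies, held 13.6 peaks per Mb in wild-type bulk, 10.6 in wild-type transfected, 6.57 in MT1, 2.57 in MT2 and 21.1 in MT4. This was between 9.96 and 16.9 times the density on the chromosome beyond 24 Mb. The density beyond 24 Mb was itself below the genome-wide density, which raises this ratio. It was 1.36, 0.63, 0.44, 0.18 and 1.25 per Mb in the same order, against 2.11, 1.52, 0.97, 0.48 and 2.85 genome-wide. The window of chromosome 5 from 140 to 141 Mb, where the protocadherin clusters lie (cell adhesion genes with many alternative first exons), had the largest mean share of peaks of all windows. It held 27 peaks in wild-type bulk, 25 in wild-type transfected, 17 in MT1, 12 in MT2 and 33 in MT4. Mutated libraries had 0.61 ± 0.22% (SD, n = 3) and wild-type libraries 0.50 ± 0.09% (SD, n = 2) of their peaks there (exact permutation p = 0.8). Chromosome 6 from 26 to 29 Mb, which holds the major histone gene cluster, took 1.2 ± 0.31% of mutant and 1.02 ± 0.04% of wild-type peaks (exact permutation p = 0.6), at 8.52 to 14.4 times the genome-wide density.

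The first pattern is the low number of MT4 peaks on chromosome 4. Poor sensitivity of the whole library is argued against by a search of every run of 10 Mb bins, which placed the largest shortfall of MT4 on chromosome 4 from 0 to 180 Mb at -13.91 SDs, where the lowest of 1000 permuted searches reached -5.7 (permutation p = 0.001, the smallest they can give), and a gap in the list by the 19 of 20 bins of 10 Mb that held an MT4 peak. An effect common to DNMT3A-mutated lines is argued against by MT1 and MT2, which held regions of both wild-type cultures 1.08 and 1.13 times as often on chromosome 4 as elsewhere, where MT4 held them 0.64 times as often. Fewer copies of chromosome 4 in MT4 cells would lower the ranks of the MT4 peaks left there. They ranked lower than in wild-type bulk by a median difference of -8.09 percentile points (95% interval -13.97 to -1.74, 112 regions). The median over all shared regions was 4.22. Chromosome 4 was in position 1 of 23 chromosomes from the lowest, although its interval overlaps that of chromosome 17 (-7.79 to 0.45). The prediction was met, but it cannot tell fewer copies from another drop in signal. Chromosome 4 was chosen for its few peaks, and any drop in signal that gives few peaks also tends to lower the ranks of the rest. Fewer copies, a methylation change in this line alone and an effect of its own DNMT3A mutation stay open. No input or copy number data were used here.

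The second pattern is the low number of wild-type transfected peaks on chromosome 7 below 60 Mb. The same search, which includes the choice of the segment, placed the largest shortfall of this library on chromosome 7 from 0 to 60 Mb at -8.47 SDs, beyond the lowest of 1000 permuted searches at -4.75 (permutation p = 0.001, the smallest they can give), which argues against poor sensitivity of the whole library. Fewer copies of this segment in these cells would lower the ranks of the peaks left there. They ranked lower than in wild-type bulk by a median difference of -35.11 percentile points (95% interval -48.86 to -24.81, 24 regions). This was position 1 of 24 from the lowest, with the next at -13.86 on chromosome 20. The lists differ in length, and the median over all shared regions was -3.65, so the segment is read against that value and not against 0. As on chromosome 4, the rank difference cannot tell fewer copies from another drop in signal. Fewer copies and a methylation change confined to the segment both stay open. The departure is in a wild-type line, so a change of this kind was not limited to mutated lines in these libraries.

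The third pattern is the few and wide peaks of MT2. If only the strongest sites had been called, and these were wide in every library, widths at the 835 regions common to all libraries should match. There MT2 peaks were 1.15 times as wide as those of wild-type bulk at the median (quartiles 1.03 to 1.34), and those of the other 3 libraries 0.94 to 0.97 times, so selection alone does not account for the width; it may account for part, since wild-type bulk peaks had a median of 1662 bp there and 1255 bp over the whole list. MT1 also had fewer and wider peaks (2842, median 1335.5 bp) than both wild-type cultures, while MT4 had more and narrower ones (8399, median 1085 bp), which argues against a trait of all 3 mutated lines; at the common regions MT1 peaks were not wider than those of wild-type bulk. Fragment length, antibody yield and depth stay open, as none is recorded in the peak lists.

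A further hypothesis was that libraries of one genotype share regions beyond what the sensitivity of each library gives. A model with 1 sensitivity per library, fitted to the combinations of libraries that held each region, expected 221 wild-type-only regions (95% range 193 to 249); 308 were observed, 1.39 times as many. For the mutant-only regions it expected 11.1 (5 to 18) and 8 were observed, 0.72 times as many, so the data met the prediction for the wild-type pair only. Other pairs departed from the model as well, so lying outside a range is weak evidence for any single combination. The fit also included the numbers it was set against. Observed numbers were above the range for wild-type bulk with MT1 (1.38 times), wild-type transfected with MT1 (1.42) and MT1 with MT2 (3.53; 10 regions against 2.84). They were below it for MT4 with wild-type bulk (0.94), with wild-type transfected (0.89) and with MT1 (0.84). Among trios, both wild-type cultures with MT1 were above the range (99 observed, 48 to 77), and wild-type transfected with MT1 and MT4 below it (80 observed, 112 to 155). At equal list length the ratio for the wild-type pair was 1.14 (69 observed, 95% range 46 to 75). The only combinations of 2 or 3 libraries above the range there were both wild-type cultures with MT4 (57 observed, 25 to 47) and with MT1 (53 observed, 25 to 47), while with MT2 they were within it (30 observed). Those below it were MT1 with MT4 (42 observed, 47 to 76) and wild-type transfected with MT2 and MT4 (22 observed, 25 to 47). The mutant trio was within its range (26 observed, 25 to 47). So the excess on the full lists was not particular to the wild-type cultures. Pairs of MT1 with either wild-type culture or with MT2 also exceeded their ranges. At equal list length the wild-type pair was within its range, while both wild-type cultures with MT1 or with MT4 were above theirs. The mutated lines as a trio were not above their range on the full lists or at equal length. With 1 wild-type pair, whether genotype is a reason for the excess of that pair stays undecided.

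Other chromosomes whose recovery lay below the library's genome-wide value by more than its 95% Wilson interval were 12, 13, 14 and X in MT1 (35.1%, 25.3%, 27.5% and 31.4%, against 43.4%) and in wild-type transfected cells (49.7%, 48.1%, 47.2% and 51.6%, against 63.5%), 12 and 19 in MT2 (12.8% and 17%, against 23%), 14 in wild-type bulk (67.9%, against 81%) and 19 and 2 in MT4 (78.2% and 79.2%, against 83.7%). These intervals were not adjusted for the number of chromosomes and libraries, so some would lie outside from counting error alone. Other chromosomes lay above in the same way: 4 in MT1, 2, 4 and 5 in MT2, 1, 6, 7 and 18 in MT4, and 1, 4 and 6 in wild-type transfected cells. The search for runs of low recovery gave permutation p-values of 0.043 for MT2 (chromosome 1 beyond 150 Mb), 0.11 for MT1 and 0.56 for wild-type bulk, unadjusted over the 5 libraries.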
